A study of Saccharomyces cerevisiae with 72 samples.

How the data were processed

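Total RNA of budding yeast was extracted with acid phenol, copied into cDNA with aminoallyl-dUTP and hybridised in 2 colours to splicing-specific oligonucleotide arrays, per the labels. The series holds 72 arrays in 11 groups, and each pair of arrays with the dyes exchanged compares the same 2 RNA extracts, so the arrays make up 36 pairs. In 5 groups a course of 6 time points was followed, with 12 arrays each. The other 6 groups are deletion strains with 1 pair each. No label says that the time points of a course came from separate cultures, and no course was repeated. The p-values given for courses therefore measure the spread between time points of 1 course, which may be technical, and not the spread between cultures.

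The authors deposited log ratios, 1 per spot, which were taken as log2 ratios. The base of the logarithm, the background correction, the normalization and the filtering of spots are not given in the sources used here. Another base would rescale every size by the same factor and leave the tests as they are. The arrays came in 2 tables of different spot numbers, 6144 spots for the 3 courses with 3-amino-1,2,4-triazole (3-AT) and 9216 spots for all other groups. The array medians lay between -0.036 and 0.035, so the arrays had been centred close to 0, and no further centring was applied. The missing share of spots was at most 0.71% in any group. Single-channel brightness was not used here, so signal over background is unknown and the number of arrays limits the precision. All tests were made within 1 table, because the tables may have been normalized separately.

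The direction of the deposited ratios is not stated. Over all probes the dye-swapped arrays of each pair correlated above 0, from 0.18 to 0.92, so both arrays already run the same way and no sign was changed. In the strains deleted for GCN2, RAI1, RRP6, SKI2, UPF1 (listed as NAM7) and XRN1 the deleted gene was far below 0, which sets the direction as mutant over wild type. Treated over untreated follows from the labels for the 3-AT courses, which share a table with the gcn2 strain. For ethanol the direction is likely and no more, since no deleted gene checks it and it rests on the labels and on the other groups of its table. RTT103 has no probe.

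The slide holds 1536 probes printed several times. The platform annotation named 1457 of them, for 982 genes, each with 1 gene symbol and none with several. The other 79 probes are unnamed here. Of the spots, 8742 of 9216 and 5828 of 6144 carry a named probe. All 1457 symbols were updated through their Entrez gene identifier with the RefSeq gene table of assembly R64, which was used for names only. No probe sequence or position was given, so no coordinates are printed. Repeated spots of a probe were averaged. Their median SD on 1 array lay between 0.083 and 0.216 in the 11 groups.

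No source names the kind of each probe (intron, junction or exon). Genes with an intron had 3 probes, and the spacing of these probes on the slide fell into 4 classes of 94, 102, 18 and 15 genes. In each class, the position that rose in prp8-1, a strain with a temperature-sensitive core splicing factor, was called the intron probe. Of 229 genes, 218 (95.2%) followed their class, and the share was the same when the direction of each class was set on one part of the genes and counted in the rest. Among the 188 genes whose difference between both positions exceeded 0.6, 184 (97.9%) followed it. The 4 that went the other way were HNT1, NOG2, RPL23A and RPL6B, whose kinds may be wrong. The partner position was called the exon probe, since the extra probe of each of 9 genes with more probes lay closest to it. The remaining probe was called the junction probe. These kinds were found by looking at the data. The fixed plan held only the step with prp8-1, and the use of spacing on the slide was added after the files were seen. The splicing design of the array is known, but no source used here states the kind probe by probe. Of the 229 genes, 96 encode ribosomal proteins and 133 do not. A further 747 genes had 1 probe, and 6 genes had several probes of unknown kind and were left out of the indices.

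The intron minus exon index of a gene is the difference between the log2 ratios of its intron and exon probes, and the junction minus exon index is built the same way. Near-identical gene copies can share a probe's signal, which is a limit for many ribosomal protein genes. The level of a gene is its exon probe or, for genes without 3 kinds, its only probe, which gave 976 levels. The fixed plan was never to test the kinds within prp8-1, which helped to define them. The prp8-1 medians of intron probes and the differences between ribosomal protein and other genes in its indices and exon probes therefore carry no p-value. Its index counts and the levels of its genes with introns are description, a departure from that plan. Its junction probes were not defined by what rose in prp8-1 and were tested.

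The tests, the alternatives, the 12 gene lists and the rule for named genes were fixed before the data were examined. Both arrays of a pair were averaged first. Each course was fitted alone with limma (lmFit and eBayes), with a mean and a linear slope on centred time, and adjusted with Benjamini-Hochberg at 0.05. Medians over genes were tested with a two-sided exact sign-flip permutation test over the 6 time points, whose smallest p is 0.0312. The response of wild type and of the gcn2 deletion to 3-AT was compared with limma, 6 time points against 6. Lists of at least 5 members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. A deletion strain with 1 pair has no test, so a list median is given with its percentile among 10000 random lists of the same size and probe kind. A limma test over the 6 strains asked which probes moved in all of them.

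The lists were genes of ribosomal proteins, amino-acid biosynthesis under Gcn4, ribosome biogenesis, heat shock and general stress, natural targets of nonsense-mediated decay, hosts of intronic snoRNAs, introns with known autoregulation, introns of meiotic genes, other housekeeping introns, the genes targeted in the strains, RNA decay factors and splicing factors. Named genes were, in each course, the 6 highest and 6 lowest past the threshold with the same sign at all 6 time points for each index and for level, and the 2 strongest members of each list in each direction. For the difference between wild type and the gcn2 deletion they were the 5 highest and 5 lowest. For each deletion strain they were the deleted gene and the 4 highest and 4 lowest genes whose arrays had the same sign and differed by less than 0.5 of their mean.

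The steps were tested on simulated data, with known changes added to noise drawn at the spread of each probe or index. For wild type in 3-AT, 86.6% of probes changed by 0.25 were recovered over 1457 probes, and 100% of those changed by 0.5 or 1, with 8.6% false among the called. For the intron minus exon index of the same course over 229 genes, 70% at 0.25, 95% at 0.5 and 100% at 1 were recovered. For prp8-1 the index recovered 45%, 65% and 100%. For ethanol it recovered 75%, 100% and 100%. For the difference between wild type and the gcn2 deletion over 1457 probes, 71.6%, 95.5% and 100% were recovered, with 7.3% false among the called.

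Alternatives were a median over spots, arrays of 1 dye orientation, median-centred arrays, all 12 arrays with the time point as a random block, no slope, the first or last 3 time points, eBayes with a trend and robust, a minimum absolute mean of 0.5, other probe sets, other set tests and each time point or strain left out. After the data were seen, spots whose value lay within 0.0005 of 6 or more other spots of their block were found, mostly of abundant transcripts. They made up 11.17% of ribosomal protein spots in prp8-1, 4.04% in ethanol, 19.19% in the rtt103 deletion and at most 0.45% in the 3-AT courses. Leaving them out was added as an alternative chosen after seeing the data. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.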

Results

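RNA abundance and splicing were followed in budding yeast on 72 two-colour arrays that carry probes for introns, splice junctions and exons. The stated scope was the splicing response to amino-acid starvation and to ethanol toxicity, and the effect of deleting mRNA decay factors that the cell can live without. In 3 courses of 12 arrays each, cells were sampled 2, 4, 6, 10, 15 and 20 min into treatment with 50 mM 3-AT. These courses compared treated with untreated wild type, treated with untreated gcn2 deletion, and the treated gcn2 deletion with treated wild type. A further course of 12 arrays compared the prp8-1 strain with wild type at 37 C over 2 to 20 min, and another followed wild type in 10% ethanol over 5 to 30 min. The label of prp8-1 gives YPD and that of its wild type names no medium, so a difference in medium is possible. The strains deleted for RAI1, RRP6, RTT103, SKI2, UPF1 or XRN1 were compared with wild type in minimal medium on 2 arrays each. Every array had a partner with exchanged dyes, and both were averaged, so that a course has n = 6 pairs and a deletion strain has n = 1 pair and no replicate. Values are log2 ratios, and their precision is limited by the number of arrays.

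The targeted genes were read first, since they check the labels. In the treated gcn2 deletion, GCN2 stood at -4.35 ± 0.086 (log2, SE, n = 6; limma adjusted p = 1.4e-08) relative to wild type. RRP6 stood at -4.01 in its own deletion, NAM7 (the UPF1 gene, a helicase of nonsense-mediated decay) at -3.50, XRN1 (the cytoplasmic 5' to 3' exonuclease) at -3.24, SKI2 (a helicase of the cytoplasmic exosome pathway) at -2.50 and RAI1 (a partner of the nuclear exonuclease Rat1) at -2.37. RTT103 had no probe, so the library labelled rtt103 deletion was not checked in this way. The PRP8 transcript, whose product carries the mutation in prp8-1, was at 0.02 in that strain (adjusted p = 0.526), which checks nothing about a point mutation. Within the treatment courses RRP6 rose by 0.45 in wild type in 3-AT and by 0.38 in the gcn2 deletion in 3-AT. Over the list of 7 targeted genes, 5 rose and 1 fell in wild type in 3-AT, and 3 rose and 1 fell in the gcn2 deletion, with camera adjusted p = 0.183 and 0.515. These counts were the same when adjusted over the list alone.

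Starvation of wild type with 3-AT, which inhibits the histidine enzyme His3, raised the intron signal of ribosomal protein genes within minutes. The median intron probe of 96 ribosomal protein genes was at 0.39 ± 0.13 (SD over n = 6 time points) and above 0 at every time, while that of 133 other intron-containing genes was at -0.061 ± 0.018 (exact sign-flip permutation p = 0.0312 for both, the smallest that 6 time points can give). Ribosome biogenesis genes rose and heat shock genes fell by camera, and both calls were lost with an estimated correlation (adjusted p = 0.422 and 0.331). Among genes of histidine synthesis, HIS5 rose by 1.14 and HIS4 by 0.91. The metallothionein CUP1-2 was the highest of the named transcripts at 1.61 ± 0.14 (SE; adjusted p = 8.97e-05), and the disaggregase HSP104 the lowest at -1.70 ± 0.21 (SE; adjusted p = 0.000324).

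The intron minus exon index rose in 72 and fell in 2 of the 96 ribosomal protein genes in wild type in 3-AT, and it rose in 60 and fell in 24 of the 133 others. The median of ribosomal protein genes exceeded that of the others by 0.21 ± 0.15 (SD, n = 6), at 6 of 6 time points (exact sign-flip permutation p = 0.0312; camera p = 8.25e-06). With an estimated correlation, camera gave p = 0.306. A median over spots gave 0.213 and the arrays with treated RNA in Cy3 alone 0.239, and neither passed (exact sign-flip permutation p = 0.0625). The difference was 0.22 at 2 min, 0.38 at 6 min and 0.008 at 20 min. By then the other genes had reached 0.19 and the ribosomal protein genes stood at 0.20, down from 0.46 at 6 min. RPS24A had the highest index at 1.18 ± 0.082 (SE; limma adjusted p = 1.08e-06), followed by RPS29B at 0.93, RPS9B at 0.93 and RPS26A at 0.92. Outside the ribosomal proteins, the index rose by 0.89 in OM14, which encodes a mitochondrial outer membrane protein and whose level fell by 1.13, and by 0.89 in PRE3, a proteasome subunit. It fell in NOG2, a GTPase of 60S assembly (-1.11, though its intron and exon probes may be exchanged), in the RNA helicase gene DBP2 (-0.52), in SMD2 of the spliceosomal core (-0.40), in APE2 (-0.25), in ACT1 for actin (-0.25) and in YRA1 for mRNA export (-0.25). In all, 158 of 229 indices passed, 132 higher and 26 lower.

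Junction signal fell in wild type in 3-AT, with medians of -0.067 in ribosomal protein genes and -0.14 in the others (exact sign-flip permutation p = 0.0312 for both), and over all genes with treated RNA in Cy3 alone it was -0.021 and did not pass (exact sign-flip permutation p = 0.312). The junction minus exon index passed in 112 of 229 genes, 30 higher and 82 lower, and the median of ribosomal protein genes minus that of the others was -0.075 ± 0.039 (SD, n = 6), below 0 at all 6 times (exact sign-flip permutation p = 0.0312; camera p = 3.44e-05). Camera gave p = 0.0397 with an estimated correlation. It fell in 45 and rose in 4 ribosomal protein genes. The lowest were RPL22B (-0.93), MPT5, which encodes a Puf family RNA-binding protein (-0.67), RPL18B (-0.60), the respiratory chain gene QCR10 (-0.56), RPL33B (-0.54) and RPS9A (-0.54). The highest were ARP2, an actin-related gene (0.71), the chromatin gene NHP6B (0.63), LSB3 (0.46), CPT1 of phospholipid synthesis (0.42), RFA2 of replication protein A (0.41) and COX4 (0.40). Exon probes of ribosomal protein genes exceeded those of the others by 0.21 ± 0.096 (SD, n = 6; exact sign-flip permutation p = 0.0312; camera p = 3.58e-11, and p = 0.0661 with an estimated correlation), with medians of 0.058 and -0.15.

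Transcript levels in wild type in 3-AT changed for 646 of 976 genes, 347 higher and 299 lower, and 936 of 1457 probes passed (limma). Most changes were small, and 158 probes and 42 intron minus exon indices had an absolute mean of 0.5 or more. Of 29 ribosome biogenesis genes, 27 rose and 1 fell, with a median of 0.45, led by DBP2 at 0.91 and DBP8 at 0.87, and GAR1 was the 1 that fell, at -0.19 (camera adjusted p = 3.79e-07). This call was lost at adjusted p = 0.422 with an estimated correlation. Their median was 0.15 at 2 min and 0.65 at 10 min. Of 10 heat shock and general stress genes, 9 fell and 0 rose by limma, with a median of -0.71. HSC82, an Hsp90 chaperone, fell by 1.31 (camera adjusted p = 0.000611 for the list, and adjusted p = 0.331 with an estimated correlation). The list's median was -0.008 at 2 min, -0.91 at 10 min and -1.30 at 20 min. Of 90 other housekeeping genes with introns, 11 rose and 49 fell, with a median of -0.11, and OM14 and the kinase gene PHO85 (-0.77) were lowest (camera adjusted p = 1.13e-05, and adjusted p = 0.331 with an estimated correlation). All 3 measured members of the list of amino-acid biosynthesis under Gcn4 rose, namely HIS4, HIS5 and the regulator gene GCN4 itself. Both natural targets of nonsense-mediated decay rose as well, PPR1 (0.43) and RPL28 (0.27).

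The other lists did not pass camera in wild type in 3-AT. Fry, which does not test a list against other genes, passed for each list below (adjusted p from 0.000273 to 0.0209). Of 123 ribosomal protein genes, 47 rose and 14 fell in level, with RPL22B at 0.83 and RPS25B at -0.26 (camera adjusted p = 0.111). Of 25 RNA decay factors, 15 rose and 8 fell, with AIR1 of the TRAMP complex at 1.30, the exosome gene RRP4 at 1.03, PAN2 at -0.35 and PAT1 at -0.33 (camera adjusted p = 0.231). Of 72 splicing factors, 31 rose and 9 fell, with PRP43 at 0.54, PRP46 at 0.43 and NAM8 at -0.37 (camera adjusted p = 0.115). Of 11 meiotic genes with introns, 2 rose and 6 fell, with MEI4 at 0.20 and REC114 at -0.29 (camera adjusted p = 0.137). Of 6 genes with autoregulated introns, 3 rose and 1 fell (camera adjusted p = 0.496). Of 8 hosts of intronic snoRNAs, 3 rose and 4 fell, with IMD4 at 0.64 and TEF4 at -0.64. Their median was -0.022 and their mean 0.06, and camera pointed down (adjusted p = 0.689). Adjusted over the list alone, ribosomal protein genes gave 43 higher and 13 lower, housekeeping genes 12 and 50, autoregulated genes 3 and 2 and splicing factors 30 and 9, and the other lists gave the counts above.

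**Figure D1:**
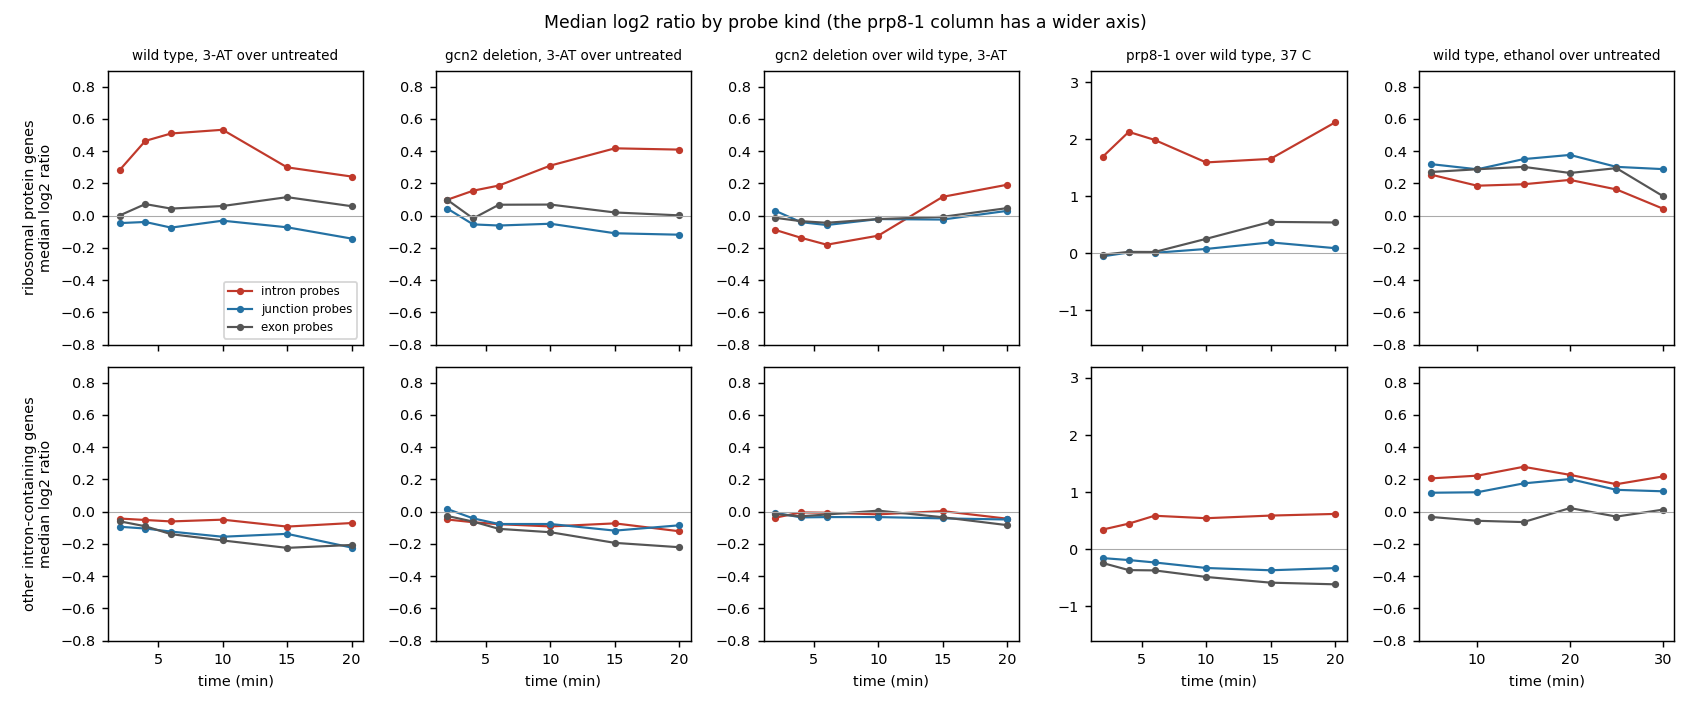
Median log2 ratio of intron (red), junction (blue) and exon (grey) probes against time in min, with 1 column for each of the 5 courses, the 96 ribosomal protein genes in the upper panels and the 133 other intron-containing genes in the lower ones. Each point is 1 time point, the prp8-1 column has a wider vertical axis, and the intron median of ribosomal protein genes in wild type in 3-AT lies above the junction and exon medians at every time, with a mean of 0.39.

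The gcn2 deletion lacks the kinase that senses uncharged tRNA and acts upstream of Gcn4, and its course asked which part of the 3-AT response goes on without it. The intron signal of ribosomal protein genes also rose in this strain. Their median intron probe was at 0.26 ± 0.14 (SD, n = 6), above 0 at every time, against -0.08 for the other genes (exact sign-flip permutation p = 0.0312 for both). Among genes with the same sign at all 6 time points, the highest levels were those of RRP4 of the exosome (1.16 ± 0.045, SE; limma adjusted p = 2.23e-07), the rRNA helicase gene DHR2 (1.10) and NOG2 (0.99, kind uncertain). HIS5 rose by 0.32 and HIS4 by 0.19. Under the same rule of sign, the lowest levels were those of OM14 (-1.30 ± 0.053, SE; limma adjusted p = 2.23e-07), SDP1 (-1.27), YPK1 (-1.01) and PHO85 (-0.87).

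The intron minus exon index passed in 144 of 229 genes of the gcn2 deletion, 106 higher and 38 lower, by limma. It rose in 60 and fell in 9 ribosomal protein genes, and rose in 46 and fell in 29 others. Ribosomal protein genes lay 0.20 ± 0.12 (SD, n = 6) above the others, at 6 of 6 time points (exact sign-flip permutation p = 0.0312; camera p = 2.72e-05), and camera gave p = 0.258 with an estimated correlation. With means in place of medians the excess was 0.182 and did not pass (exact sign-flip permutation p = 0.0625). Their median index was -0.025 at 2 min, 0.26 at 10 min and 0.42 at 20 min, so that it stood highest at the end of the course, where wild type had its maximum at 6 min. The largest indices were OM14 (1.08 ± 0.059, SE; adjusted p = 6.05e-08), RPS24A (1.03), PHO85 (0.99), RPL20B (0.79), RPS13 (0.68) and RPL21A (0.66). The lowest were NOG2 (-1.38) and HNT1 (-0.36), whose kinds may be wrong, IMD4 (-0.59), the kinase regulator gene MOB2 (-0.48), SMD2 (-0.39) and YRA1 (-0.36). The junction minus exon index passed in 97 genes, 37 higher and 60 lower, with OM14 (1.33), ARP2 (0.92), COX4 (0.85), LSB3 (0.57), TMH18 (0.47) and PFY1 (0.44) highest and RPL22B (-0.64), MPT5 (-0.60), MOB2 (-0.53), RPL18B (-0.46), YNL050C (-0.45) and RPS27A (-0.39) lowest. Ribosomal protein genes fell in 39 and rose in 4 cases, and lay below the others by a median of -0.12 ± 0.044 (SD, n = 6; exact sign-flip permutation p = 0.0312; camera p = 0.0194 with an estimated correlation). Their exon probes exceeded the others by 0.16 (exact sign-flip permutation p = 0.0312; camera p = 2.56e-08, and p = 0.0763 with an estimated correlation).

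By level, 596 of 976 genes passed in the gcn2 deletion in 3-AT, 321 higher and 275 lower, and 831 of 1457 probes did (limma). Of 29 ribosome biogenesis genes, 27 rose and 0 fell, with a median of 0.53 and DBP8 at 1.02 (camera adjusted p = 2.06e-10, and adjusted p = 0.162 with an estimated correlation). Of 90 housekeeping genes with introns, 13 rose and 46 fell, with a median of -0.11 (camera adjusted p = 9.25e-05, and adjusted p = 0.162 with an estimated correlation). Of 10 heat shock genes, 1 rose, SSA3 at 0.13, and 5 fell, with HSP104 at -0.80 and GPD1 at -0.70 (camera adjusted p = 0.272). Of 123 ribosomal protein genes, 35 rose and 13 fell, with RPS9A at 0.61 and RPS31 at -0.51 (camera adjusted p = 0.272). Of 25 decay factors 14 rose and 5 fell, and of 72 splicing factors 29 rose and 11 fell, with PRP43 at 0.65 and NAM8 at -0.45 (camera adjusted p = 0.177 for both). Hosts of snoRNAs rose in 2 and fell in 3 of 8 cases, with a median of -0.032, a mean of 0.118 and camera pointing down at adjusted p = 0.999. Meiotic genes rose in 1 and fell in 4 of 11 cases, autoregulated genes rose in 3 and fell in 1 of 6, and 2 of 3 Gcn4 genes and 2 of 2 decay targets rose. Adjusted over the list alone, ribosomal protein genes gave 33 higher and 10 lower, housekeeping genes 13 and 47, decay factors 14 and 6 and autoregulated genes 3 and 2, and the rest were as above. No slope term brought the count of probes to 472, and the count of junction indices over the first 3 time points was 0 by limma, with 42 at an unadjusted p under 0.05.

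Wild type and the gcn2 deletion differed in their response to 3-AT, with a larger rise of HIS4 and HIS5 in wild type and a larger fall of 8 of 10 heat shock genes, by limma with a slope term. Without that term 0 probes passed (limma, 209 at an unadjusted p under 0.05), and 6 of 100 splits of the time points gave as many probes with it, so the named differences are provisional. HIS4 was at 0.91 in wild type and 0.19 in the deletion, a difference of 0.72 ± 0.068 (SE, n = 6 time points each; limma adjusted p = 9.8e-05). HIS5 differed by 0.82 ± 0.075 (adjusted p = 9.8e-05), the transcription factor gene MET28 by 0.87 ± 0.093 (adjusted p = 0.000197, higher in wild type at 3 of 6 time points), MET22 by 0.68 and CUP1-2 by 0.76. HSC82 stood at -1.31 in wild type and -0.32 in the deletion (difference -0.99 ± 0.15, SE; adjusted p = 0.00111), and the difference was -0.79 for the Hsp40 gene SIS1, -0.90 for HSP104 (adjusted p = 0.0499), -0.70 for the glycolytic regulator TYE7 and -0.60 for the Ran gene GSP1. On the arrays of the deletion directly over wild type in 3-AT, CUP1-2 (-0.071) hardly differed and GSP1 (-0.092) went the other way. The other genes named here lay on the side of the difference there. Of 10 heat shock genes, 0 responded more highly in wild type and 8 less (median -0.50; camera adjusted p = 4.48e-07), a call lost at adjusted p = 0.119 with an estimated correlation. All 3 Gcn4 genes, GCN4 itself among them, responded more in wild type, with a median difference of 0.72.

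The splicing indices of few genes passed in the difference between both strains. Intron minus exon indices passed in 30 of 229 genes, 27 higher in wild type and 3 lower, but in 0 without the slope term (limma, 32 at an unadjusted p under 0.05), and 6 of 100 splits of the time points gave as many. Among them were CPT1 (0.54 in wild type and 0.002 in the deletion), RPS9A (0.05 and -0.47), RPS29B (0.93 and 0.51), SAC6 (0.57 and 0.18) and DBP2 (-0.52 and -0.11). The arrays of the deletion directly over wild type in 3-AT did not bear these out. They gave -0.014 for CPT1, 0.47 for RPS9A, 0.008 for RPS29B, -0.11 for SAC6 and -0.044 for DBP2. Those arrays also hold what differed before treatment. The junction minus exon index passed in 20, 6 higher in wild type and 14 lower, and in 2 without the slope term, with MOB2 (-0.021 and -0.53) and ERV1 (-0.056 and 0.33) among them. Averaged over time, no difference in the excess of ribosomal protein over other genes was detected, at 0.21 in wild type and 0.20 in the deletion (difference 0.013, exact permutation p = 0.872, two-sided, n = 6 each). This mean joins values that went both ways, with 0.22 in wild type and 0.005 in the deletion at 2 min, 0.38 and 0.14 at 6 min, 0.068 and 0.28 at 15 min, and 0.008 and 0.34 at 20 min. For the junction index the difference was 0.045 (exact permutation p = 0.0931). Over levels, 178 of 976 genes differed, 92 with the higher response in wild type and 86 with the lower. By list, 8 ribosomal protein genes responded higher and 3 lower in wild type, 6 and 15 housekeeping genes, 5 and 5 splicing factors, 2 and 2 decay factors, and at most 3 in any other list but heat shock and Gcn4 (camera adjusted p from 0.479 to 0.838). The count of 244 differing probes was 66 without the 15 min time point, 107 without 20 min, 117 without 10 min and 146 without 6 min, and 0 without the slope term by limma, with 209 at an unadjusted p under 0.05. The count of 30 intron indices was 5 without 15 min, 6 without 6 min, 7 without 10 min, 11 without 4 min and 16 without 20 min, and the 20 junction indices fell to 0 without 15 or 20 min (43 and 41 at an unadjusted p under 0.05, limma), 3 without 10 min, 7 without 6 min and 8 without 4 min.

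**Figure D2:**
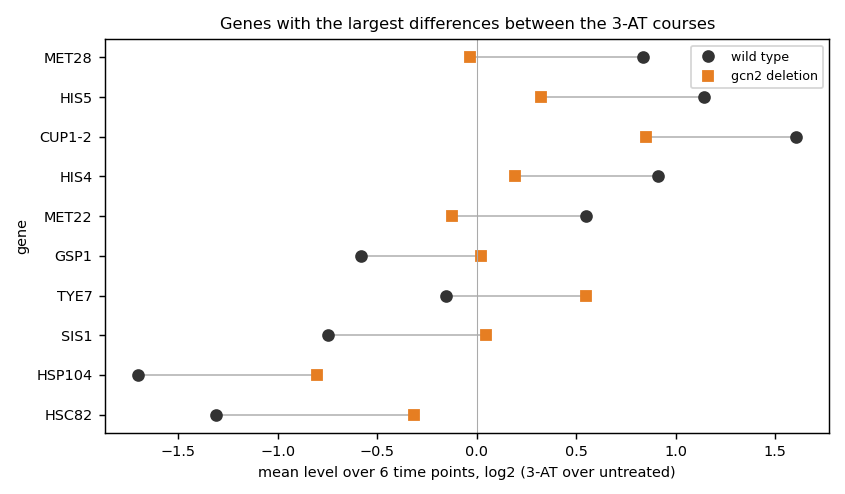
Mean log2 level over 6 time points in 3-AT over untreated cells, for wild type (black circles) and the gcn2 deletion (orange squares), for the 10 named genes whose response differed. HIS5 lies at 1.14 in wild type and 0.32 in the deletion, and HSC82 at -1.31 and -0.32.

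Set directly against wild type with both in 3-AT, the gcn2 deletion had lower HIS4 and HIS5 and higher HSC82 and HSP104. HIS4 was at -1.64 ± 0.045 (SE, n = 6; limma adjusted p = 1.01e-07), HIS5 at -1.44, MET28 at -1.35, SPL2 at -1.10 and the tRNA gene SUP16 at -1.07. HSC82 was at 1.46 ± 0.054 (adjusted p = 7.12e-07), HSP104 at 1.14, MF(ALPHA)2 for alpha-factor at 1.09, the Hsp70 gene SSA1 at 0.89, SIS1 at 0.88 and the aldehyde dehydrogenase gene ALD3 at 0.85. Of 10 heat shock genes 9 were higher and 0 lower by limma, or 10 and 0 adjusted over the list alone, with a median of 0.79 (camera adjusted p = 1.34e-05, and adjusted p = 0.071 with an estimated correlation). Of 29 ribosome biogenesis genes 18 were higher and 2 lower, with SPB1 at 0.49 and NOP1 at -0.21 (camera adjusted p = 0.00959, and adjusted p = 0.527 with an estimated correlation). All 3 Gcn4 genes were lower.

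Averaged over time, no preference for ribosomal protein introns was detected in this direct comparison, but their direction turned during the course. Their median intron minus exon index was at -0.095 at 2 min, -0.17 at 6 min and 0.17 at 20 min, at percentiles 0.5, 0 and 99.9 among random lists. Their intron median was at -0.037 ± 0.15 (SD, n = 6; exact sign-flip permutation p = 0.562), and it went from -0.18 at 6 min to 0.19 at 20 min. The intron minus exon index passed in 98 genes, 50 higher and 48 lower, and differed between ribosomal protein and other genes by -0.032 (exact sign-flip permutation p = 0.469). RPL30 (0.67 ± 0.053, SE; adjusted p = 1.72e-08), RPL22B (0.62), RPS22B (0.58), RPL18B (0.53), RPS13 (0.51) and RPS9A (0.47) were highest, and NOG2 (-0.74, kind uncertain), RFA2 (-0.64), MRPL44 (-0.57), DCN1 (-0.45), SRB2 of Mediator (-0.44) and TEF4 (-0.42) lowest. The junction minus exon index passed in 76 genes, 39 higher and 37 lower, and in 49 without the 10 min time point, with RPS9A (0.90) and COX4 (0.76) highest and RFA2 (-0.60) and MOB2 (-0.42) lowest. By level 570 of 976 genes passed, 334 higher and 236 lower, and 744 of 1457 probes did. Ribosomal protein genes were higher in 25 and lower in 34 cases, with RPL38 at 0.46 and RPL7B at -0.83, splicing factors in 27 and 7 of 72, decay factors in 13 and 2 of 25, housekeeping genes in 21 and 30 of 90, snoRNA hosts in 3 and 4 of 8, autoregulated genes in 1 and 5 of 6, meiotic genes in 0 and 3 of 11, and decay targets in 1 and 1 of 2 (camera adjusted p from 0.057 to 0.21 for those tested). Adjusted over the list alone, decay factors gave 14 and 2, housekeeping genes 21 and 31, and targeted genes 5 and 1 against 4 and 1 over all. The targeted genes had a median of 0.107 and a mean of -0.495, with GCN2 itself among them, and camera pointed up (adjusted p = 0.336). Across 1457 probes, which are not independent replicates, the direct ratio correlated with the difference of both responses at 0.02 at 2 min and at 0.73 at 20 min. The direct ratio also holds what differed between the strains before treatment, and RPS9A, whose index is higher in the deletion here, had the lower response in it.

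The prp8-1 strain carries a temperature-sensitive form of the core splicing factor Prp8, and its course at 37 C asked which introns accumulate when splicing is blocked. Intron signal was above wild type in both classes at every time point. The median intron probe was at 1.89 ± 0.29 (SD, n = 6) in ribosomal protein genes and at 0.52 ± 0.11 in the others, with no p, because this strain helped to define the intron probes. SEC17, the yeast alpha-SNAP, had the largest intron minus exon index at 4.94 ± 0.14 (SE), with its level at -3.32, followed by the ubiquitin-conjugating enzyme gene UBC4 (2.98), RPL19B (2.97), RPL27A (2.95), the phosphatase gene GLC7 (2.89) and SAC6 for fimbrin (2.86). The index lay past the threshold in 213 of 229 genes as a description, 205 higher and 8 lower. Among the lower ones were NOG2 (-2.12), HNT1 (-1.26), RPL6B (-1.07) and RPL23A (-1.05), whose kinds may be wrong, and AMA1 (-0.57) and UBC12 (-0.43), whose sign turned on the arrays of 1 dye orientation.

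The excess of ribosomal protein over other genes in the intron minus exon index of prp8-1 was 0.59 ± 0.50 (SD, n = 6), at 5 of 6 time points, and 0.724 with the mutant in Cy5 alone, again with no p. Junction signal fell slightly, with a median of -0.13 ± 0.028 over all 229 genes (exact sign-flip permutation p = 0.0312), but it was -0.207 with the mutant in Cy3 and -0.034 with it in Cy5. The fall lay in the other genes, at -0.27 ± 0.087 (SD, n = 6; exact sign-flip permutation p = 0.0312). In ribosomal protein genes the junction median was 0.054 ± 0.084 (exact sign-flip permutation p = 0.156). The junction minus exon index lay past the threshold in 174 genes as a description, 69 higher and 105 lower. Ribosomal protein genes lay below the others, with a difference of medians of -0.14 ± 0.12 (SD, n = 6), and -0.101 with the mutant in Cy3 alone, with no p, because the exon probes were also defined with this strain. RPL35B (-3.01 ± 0.051, SE), RPL43B (-1.88), RRT8 (-1.45), MPT5 (-1.33) and RPS9A (-1.09) were lowest, and OM14 (2.54), SEC17 (2.16), MRK1 (1.68), TMH18 (1.54), UBC5 (1.47) and SCS22 (1.36) highest. Exon probes were at 0.23 in ribosomal protein genes and at -0.44 in the others, a difference of 0.67 ± 0.40 (SD, n = 6), again with no p.

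Levels in prp8-1 passed in 762 of 976 genes, 332 higher and 430 lower, and 1152 of 1457 probes did. Mating-type transcripts were among the largest changes. The a-factor genes MFA2 and MFA1 were at 4.26 and 2.21, and MF(ALPHA)1, MF(ALPHA)2 and the a-factor receptor STE3 at -5.97, -3.88 and -3.78, and this difference between the strains stands beside every gene group of this comparison. So does the medium, which the labels name for prp8-1 (YPD) and not for its wild type. Its part in these levels cannot be told apart from that of the mutation. ASP3-1 was at 2.93, PPR1 at 2.15, IMD4 at 1.92 and AFT1 at 1.78, and GAC1 was at -3.50 and the GAPDH gene TDH1 at -3.28. Ribosomal protein genes were higher in 83 and lower in 5 of 123 cases, with RPL26A at 1.01 and RPS22B at -0.98, as a description, since their levels are exon probes where they have introns. Ribosome biogenesis genes were higher in 26 and lower in 0 of 29 cases by limma, with CBF5 at 1.51 and RLP7 at 1.40 (camera adjusted p = 7.56e-09, and adjusted p = 0.26 with an estimated correlation). Housekeeping genes with introns were higher in 12 and lower in 68 of 90 cases, led downwards by SEC17 and OM14, as a description for the same reason. Heat shock genes were higher in 1 and lower in 8 of 10 cases, with ALD3 at -3.10 and SSA3 at -2.78 (camera adjusted p = 0.0681). As a description, snoRNA hosts were higher in 6 and lower in 1 of 8 cases, autoregulated genes in 5 and 1 of 6 and meiotic genes in 1 and 7 of 11. Decay factors were higher in 13 and lower in 9 of 25 cases, with PAT1 at -1.56 and a median of 0.078, a mean of -0.062 and camera pointing up (adjusted p = 0.39). Splicing factors were split into 27 and 26 of 72, with PRP43 at 0.94 and PRP6 at -0.94, a median of -0.002, a mean of 0.021 and camera pointing up (adjusted p = 0.263). All 3 Gcn4 genes were lower, 1 of 2 decay targets was higher, and 4 targeted genes were higher and 1 lower. Every list gave the same counts when adjusted over the list alone.

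**Figure D3:**
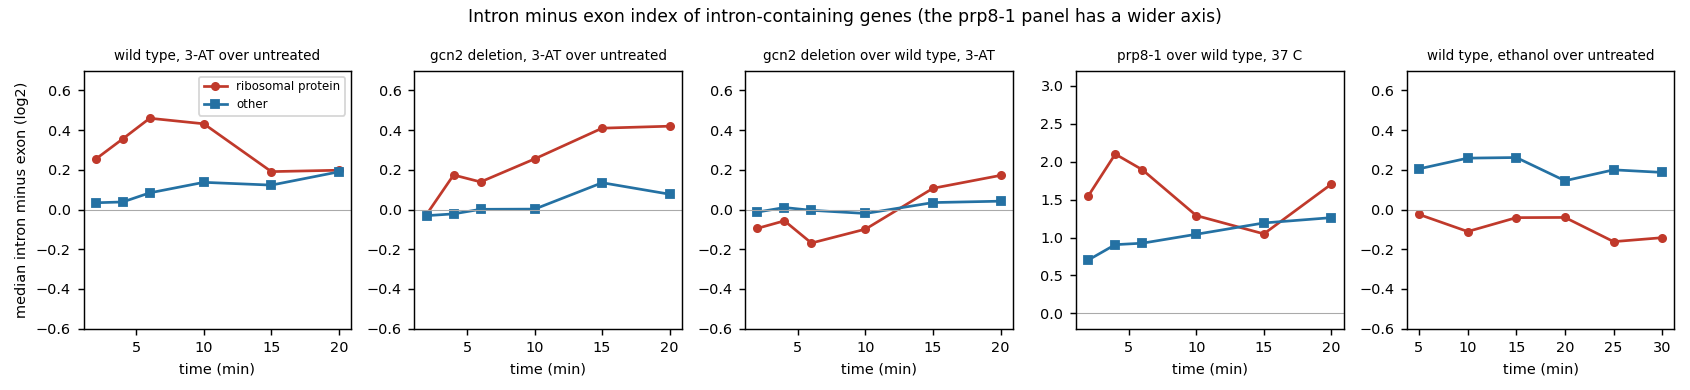
Median intron minus exon index (log2) against time in min in the 5 courses, for 96 ribosomal protein genes (red circles) and 133 other genes (blue squares), with a wider vertical axis for prp8-1. In wild type in 3-AT the ribosomal protein median is 0.46 at 6 min and 0.20 at 20 min, and in ethanol it lies below the other genes at all 6 times.

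In ethanol, EFT1 and SSA1 had the lowest levels and several genes outside the ribosomal proteins rose in the intron minus exon index, if the ratios run as treated over untreated, which is likely and was not checked by a deleted gene. With the ratios turned every sign of this course would change. EFT1 for elongation factor 2 was at -3.37 ± 0.19 (SE, n = 6; limma adjusted p = 6.42e-07), the Hsp70 genes SSA1 and SSA2 at -3.15 and -2.59, TEF4, a subunit of elongation factor 1B, at -2.40, TIF1 for eIF4A at -2.28 and SSB1, a ribosome-associated Hsp70, at -2.10, while the Hsp70 gene SSA3 rose by 0.17 (adjusted p = 0.0121). The intron minus exon index of TEF4 was at 4.46 ± 0.083 (adjusted p = 1.01e-15), that of ACT1 at 2.25, of PMI40 at 2.11, of the cell wall gene ECM33 at 2.01, of DBP2 at 1.84 and of NOG2 (kind uncertain) at 2.54. The lowest indices were those of the V-ATPase gene VMA10 (-1.73), DCN1 (-1.61), SRB2 (-1.57), RPL37B (-1.54), RPL22A (-1.41) and RPL42B (-1.39). The 6 highest of the named levels were those of tRNA genes.

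Ribosomal protein genes lay below other genes in the intron minus exon index in ethanol, with medians of -0.087 and 0.21 and a difference of -0.30 ± 0.075 (SD, n = 6), at 6 of 6 time points (exact sign-flip permutation p = 0.0312; camera p = 0.00044, and p = 0.0722 with an estimated correlation). The index rose in 34 and fell in 45 ribosomal protein genes, and rose in 72 and fell in 28 others. Intron probes alone were above 0 in both classes, at 0.18 and 0.22, and junction probes at 0.32 and 0.15 (exact sign-flip permutation p = 0.0312 for each), while exon probes were at 0.26 in ribosomal protein genes (exact sign-flip permutation p = 0.0312) and at -0.025 in the others (exact sign-flip permutation p = 0.188). Over all genes, on the arrays with treated RNA in Cy5 alone, the junction median was 0.066 and no longer passed (exact sign-flip permutation p = 0.125), and the exon median turned to -0.004. In all 179 of 229 intron indices passed, 106 higher and 73 lower, and 178 junction indices, 111 higher and 67 lower. Junction indices were highest in ECM33 (2.60), RPS30A (2.41), RPL22B (1.75), ARP2 (1.44), HMRA1 (1.27) and SAC6 (1.26), and lowest in NMD2, the UPF2 gene (-2.25), RPS26A (-0.99), RPS30B (-0.93), VMA10 (-0.92), HOP2 (-0.89) and UBC8 (-0.86). The slope over 5 to 30 min passed for 2 probes and for 0 intron indices by limma, with 107 and 30 at an unadjusted p under 0.05.

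By level 792 of 976 genes passed in ethanol, 305 higher and 487 lower, and 1188 of 1457 probes did. Of 29 ribosome biogenesis genes 3 rose and 23 fell, with NOP1 at -1.97, NOP58 at -1.86 and RRP1 at 0.58 (camera adjusted p = 0.0015, and adjusted p = 0.5 with an estimated correlation). Of 123 ribosomal protein genes 62 rose and 43 fell, with RPL39 at 1.91, RPL37B at 1.62, RPL4B at -2.06 and RPL4A at -1.81 (camera adjusted p = 0.0015, and adjusted p = 0.5 with an estimated correlation). Of 72 splicing factors 33 rose and 24 fell, with SLU7 at 1.02, LSM5 at 0.92, DIB1 at -1.98 and SME1 at -1.72 (camera adjusted p = 0.0337, and adjusted p = 0.39 with an estimated correlation). All 7 targeted genes fell, from -0.23 in SKI2 to -0.79 in NAM7 (camera adjusted p = 0.075). Heat shock genes rose in 2 and fell in 7 of 10 cases, with ALD3 at 0.22 (camera adjusted p = 0.0846). Decay factors rose in 5 and fell in 15 of 25 cases, with DHH1 at -1.71, snoRNA hosts in 2 and 6 of 8, meiotic genes in 6 and 3 of 11, Gcn4 genes in 0 and 3 of 3 with GCN4 at -1.35, and decay targets in 1 and 0 of 2 (camera adjusted p from 0.154 to 0.32 for those tested). Autoregulated genes were split into 2 and 2 of 6, with a median of 0.009, a mean of -0.044 and camera pointing up (adjusted p = 0.666), and housekeeping genes into 34 and 44 of 90, with VMA10 at 1.53, ECM33 at -2.09, a median of -0.095, a mean of -0.203 and camera pointing up (adjusted p = 0.774). Adjusted over the list alone, ribosome biogenesis gave 3 higher and 24 lower and meiotic genes 6 and 4, and the rest were the same.

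The deletions of decay factors asked which spliced and unspliced RNAs each factor removes. With 1 pair per strain there is no test, and all values of these strains describe those libraries. Of 120 list medians computed, 20 per strain, those given here were picked after their values were seen. In the strain lacking RRP6, the nuclear exosome exonuclease, introns that host snoRNAs stood out, with a median intron minus exon index of 1.28 over 8 genes, at percentile 100 among 10000 random lists of the same size (1.42 and 1.33 on the 2 arrays). The same list was at 0.39 without UPF1 (percentile 98.1), with 0.066 and 0.41 on the arrays and a mean over genes of 0.101, and at 0.29 in the rtt103 deletion (percentile 99.5), with 0.15 and 0.33 on the arrays. It was at -0.10 without SKI2 and -0.12 without RAI1, above 0 on 1 array of each, and at -0.44 without XRN1 (percentile 5.4, with -0.64 and -0.099). Without RRP6, the intron minus exon index of RPS22B was 2.49, of RPS9A 2.26, of RPL7B 1.75, of RPL18B 1.61 and of HOP2 -1.68. The level of SUF10 in that strain was 3.05. In the strain lacking UPF1 and in that lacking XRN1, the intron of RPL28, a known target of nonsense-mediated decay, had an index of 1.92 and 2.60, that of CPT1 1.62 and 1.91 and that of NHP6B 1.47 and 1.44. YRA1 stood at 1.59 in the strain lacking XRN1, and DCN1 at -1.82, NOG2 (kind uncertain) at -1.62, RPL27A at -1.35 and RPL25 at -1.21.

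Meiotic genes had low junction minus exon indices in the same strains, with medians of -0.58 without UPF1 and -1.02 without XRN1 over 10 genes (-1.07 and -0.55, and -1.46 and -0.57 on the arrays), at percentile 0 among random lists, and from -0.099 to 0.034 in the other 4. Their intron minus exon medians were -0.17 without UPF1 (percentile 10.9) and -0.29 without XRN1 (percentile 12.1). Level medians over 11 meiotic genes were 0.31 in both strains (percentiles 99.3 and 97.5), with 0.089 on 1 array without XRN1. The low junction index thus stood beside a higher level, with no rise of the intron minus exon index. The junction minus exon index of REC107 was -2.16 without UPF1, where its level was 2.15, and -1.59 without XRN1. That of REC114 was -1.35 without UPF1 and that of HFM1 -1.25 without XRN1. The index was also low in other genes, in RPL22B at -1.40 without UPF1 and -1.83 without XRN1. It was -1.11 in MAF1 without UPF1 and -1.44 in MTR2 without XRN1. Genes with autoregulated introns had median intron minus exon indices of 0.95 without XRN1 (percentile 99.9, with 1.18 and 0.57 on the arrays), 0.87 without RAI1 (percentile 100, with 1.10 and 0.49), 0.65 without RRP6 (percentile 99.7, with 1.01 and 0.28) and 0.50 without UPF1 (percentile 98.9), of 0.012 in the rtt103 deletion (percentile 52.5) and of -0.32 without SKI2 (percentile 8.4, with -0.013 and -0.43). Their level medians differed, at 0.98 without XRN1 (percentile 100) and -0.54 without RAI1 (percentile 0), so a low exon signal enters the index without RAI1. They were -0.19 without RRP6, 0.009 without UPF1, 0.19 in the rtt103 deletion and -0.034 without SKI2. Without RAI1, the intron minus exon index was highest in HNT2 (1.34), RPL18B (1.26), RPS14B (1.13) and RPL22B (0.93), and lowest in RPL19A (-0.89), RPL21A (-0.88), YRA1 (-0.83) and RPS10B (-0.81). Ribosomal protein genes had low medians in 5 of 6 strains, at -0.31 without RAI1, -0.28 without SKI2, -0.078 in the rtt103 deletion (0.018 with the mutant in Cy3) and -0.073 without RRP6 (0.047 as a mean over genes; percentile 0 for each median), and at -0.17 without XRN1 (percentile 0.6, and -0.069 with the mutant in Cy3), against 0.048 without UPF1 (percentile 76.4). Without SKI2, EFB1 was at 0.90 and RPL2A at -0.71. In the rtt103 deletion the index spread least between genes (SD 0.25), with CPT1 at 0.86 and MRK1 at -0.51. By level, ribosome biogenesis genes had medians of -0.51 without UPF1 and -0.51 without XRN1 (percentile 0 for both), and lay at percentile 0 without RAI1 and RRP6, 0.2 in the rtt103 deletion (-0.16) and 31.6 without SKI2 (-0.019). Heat shock genes had medians of 0.79 without XRN1, 0.57 without UPF1, 0.44 without SKI2, 0.36 without RAI1 and 0.19 in the rtt103 deletion (percentiles 99.5 to 100, with 0.087 on 1 array of rtt103), and of 0.11 without RRP6 (percentile 83). Splicing factors were at 0.43 without XRN1, 0.21 without RAI1 and 0.13 without UPF1 (percentile 100 for each, with -0.050 on 1 array of UPF1), at percentile 99.5 without RRP6 (0.22 and -0.002 on the arrays), and at 0.024 without SKI2 and -0.001 in the rtt103 deletion. Both arrays agreed on a level above 1 for 68 genes and below -1 for 32 genes without XRN1, among them SPL2 at 3.55 and ADA2 at 2.59, and for 33 and 10 without UPF1, with CTL1 at 2.36. NAM7 stood at 0.92 without XRN1. The mating-type genes described for prp8-1 differed in these strains too.

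**Figure D4:**
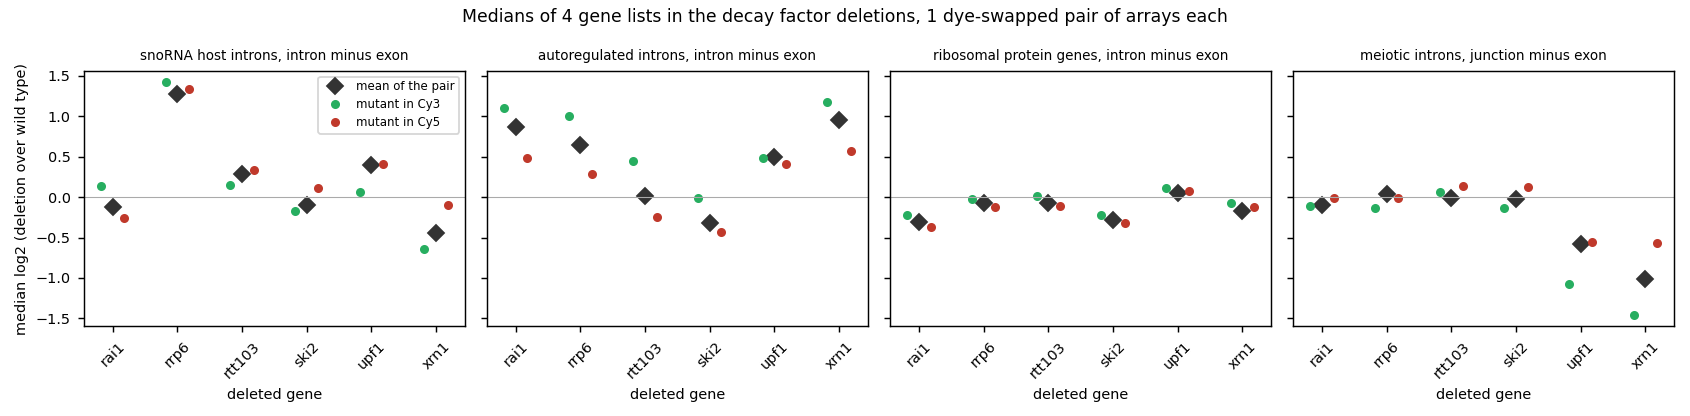
List medians (log2) in the 6 deletion strains, with panels for the intron minus exon index of snoRNA hosts, autoregulated and ribosomal protein genes and the junction minus exon index of meiotic genes. Diamonds are means of the pair and green and red points the arrays with the mutant in Cy3 and Cy5, and snoRNA hosts reach 1.28 in the strain lacking RRP6.

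Across all 6 deletions, 200 of 1457 probes moved in common, 82 higher and 118 lower, and 471 had an unadjusted p under 0.05 (limma, n = 6 strains). Mating-type genes were among them, with MFA2 at 5.39 ± 0.095 (SE; adjusted p = 5.04e-08), MFA1 at 4.55, STE3 at -4.28 and MATALPHA1 at -2.39, and both alpha-factor genes were lower in all 6 strains. The transcription factor gene CIN5 was at 1.57, SPL2 at 2.72 and SIS1 at 0.61, all higher in 6 of 6 strains. Of intron minus exon indices 31 passed, 14 higher and 17 lower, and of junction minus exon indices 28, 19 higher and 9 lower. A wild-type RNA shared by the 6 pairs would add the same error to all strains. The count was 71 with trend and robust eBayes, and 538 and 404 with the mutant in Cy3 or in Cy5 alone. It was 68 without the rrp6 deletion, 80 without rai1, 89 without rtt103 and 93 without upf1.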

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

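The counts over other splits of the samples were planned, and all other tests of explanations in this part were chosen only after the result was seen.

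The response to 3-AT differed between wild type and the gcn2 deletion in a direct test of the difference, by 244 probes, 30 intron minus exon indices and 20 junction minus exon indices (limma). Of the 462 splits of the 12 time points, 100 were drawn, without regard to the minute of sampling. For probes 6 of 100 gave as many, up to 403, and for the intron index 6 of 100, up to 59, so chance can not be excluded for these counts. For the junction index 1 of 100 did, the real one, with 17 as the highest of the others, so few splits of these time points reach this count. The courses were not repeated, so this cannot exclude chance between cultures. The junction count was also unstable, at 2 without the slope term (limma). Without the 15 min time point the counts were 66, 5 and 0, without 20 min 107, 16 and 0, without 10 min 117, 7 and 3, without 6 min 146, 6 and 7, and without 4 min 11 intron and 8 junction indices. By limma, 43 and 41 junction indices had an unadjusted p under 0.05 without 15 and 20 min.

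The genes named for this difference are given as wild type minus deletion. By level they were MET28 at 0.867, HIS5 at 0.82, CUP1-2 at 0.756, HIS4 at 0.721 and MET22 at 0.678, and HSC82 at -0.993, HSP104 at -0.9, SIS1 at -0.793, TYE7 at -0.701 and GSP1 at -0.599. In the intron minus exon index they were CPT1 at 0.542, RPS9A at 0.519, YNL050C at 0.479, RPS29B at 0.424 and SAC6 at 0.399, and DBP2 at -0.411, TAD3 at -0.333 and HAC1 at -0.236. The direct comparison of the deletion over wild type did not bear these indices out. It gave 0.473 for RPS9A and values from -0.105 to 0.021 for the others. In the junction minus exon index they were MOB2 at 0.513, CPT1 at 0.342, RFA2 at 0.329, ARF2 at 0.204 and SAR1 at 0.178, and ATG38 at -0.541, DMC1 at -0.444, COX4 at -0.444, ERV1 at -0.381 and RPL7B at -0.312. The heat shock list differed as a set (camera adjusted p = 4.48e-07, and adjusted p = 0.119 with an estimated correlation).

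In 45 groups of 6 time points searched for a single value far from the others, 4 were found, where chance alone gives about 1 in 20, or 2.25. In the direct comparison of both strains they were the junction median of genes other than ribosomal protein genes at 2 min (-0.007), and the ribosomal protein minus other difference at 20 min in the junction minus exon index (-0.05) and in exon level (0.131). In ethanol it was the exon median of ribosomal protein genes at 30 min (0.122). The 79 probes without a gene name, which entered no comparison, also moved, with 32 past the threshold in wild type in 3-AT, 38 in the gcn2 deletion, 26 in the direct comparison, 57 in prp8-1 and 65 in ethanol.

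Each course had 32 sign flips of its 6 time points, and only the real one gave a count as large. Time points of 1 course may share cultures, and a lasting offset between the compared RNAs keeps 1 sign. These flips thus cannot exclude chance, and no course was repeated. In wild type in 3-AT the real counts of probes, intron and junction indices were 936, 158 and 112, with 666, 71 and 54 as the highest of the other flips. In the gcn2 deletion they were 831, 144 and 97 against 737, 127 and 64, and in the direct comparison 744, 98 and 76 against 227, 28 and 0. In prp8-1 they were 1152, 213 and 174 against 255, 0 and 97, with index counts as description, since it helped to define the probe kinds. In ethanol the counts were 1188, 179 and 178 against 0 for each. For probes moved in common over the 6 deletions, 1 of 32 flips of the strains gave as many, with 200 in the real one and 1 as the highest other.

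Mating-type genes differed in prp8-1 and in the 6 deletions. In 7 of 7 of these comparisons MFA1 and MFA2 were above 1 and MF(ALPHA)1, MF(ALPHA)2, STE3 and MATALPHA1 below -1. MATALPHA2 was below -1 in prp8-1 alone (-1.68), from -0.891 to -0.761 in 4 deletions, and above 0 without UPF1 (0.458) and XRN1 (0.415), so 1 of 7 met this with it. The 6 other genes thus went the way of a wild-type partner of the opposite mating type in 7 of 7 comparisons. Such a partner stays open here because of MATALPHA2 alone. The gcn2 deletion against wild type, also a comparison between strains, did not show the pattern, with MFA1 at 0.077, MFA2 at 0.179, MF(ALPHA)1 at 0.744 and MF(ALPHA)2 at 1.09. The median of the 6 genes other than MATALPHA2, signed by that direction, was from 3.83 in prp8-1 to 4.71 in the ski2 deletion, and at most 0.202 in the 3 courses that compare a strain with itself. Without all 7 genes 194 probes were left in common over the deletions, so 1 wild-type RNA shared by the 6 deletions may add to them, and this cannot be told apart from a common effect of deletion, since no label says whether the RNA was shared.

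Intron signal of ribosomal protein genes was high in 3-AT. A fall of the exon signal is argued against by the intron probes alone, with a median of 0.389 ± 0.052 (SE, n = 6) in wild type and 0.263 ± 0.056 in the gcn2 deletion. Compression of bright exon spots would leave the intron probes as they are. Brightness was not used, so its part in the intron minus exon index stays open. Cross-hybridisation between gene copies is argued against in wild type, where 7 single-copy ribosomal protein genes still exceeded other genes by 0.173 ± 0.028 (SE, n = 6; exact sign-flip permutation p = 0.0312), against 0.217 for 89 copied ones. In the gcn2 deletion the single-copy genes gave 0.146 ± 0.063 (exact sign-flip permutation p = 0.0938), so cross-hybridisation could account for part of it there and stays open. A change in splicing of these genes, or in the decay of their introns, stays open and was not tested.

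Ribosomal protein genes lay above other genes in the intron minus exon index in wild type in 3-AT (0.214) and below them in ethanol (-0.296), at every time point in each course, and the difference between the treatments was not tested, since the tables may have been normalized separately. The opposite signs rest on the direction of the ethanol ratios, which is likely and no more, and with the ratios turned the difference in ethanol would be 0.296, above 0 as in 3-AT. For ethanol, intron probes alone differed by -0.043 ± 0.077 (SD, n = 6; exact sign-flip permutation p = 0.25) and exon probes by 0.283, which is consistent with the exon level, not the intron signal, setting the index. Saturated spots of abundant transcripts stay open. The difference was -0.311 without spots at a piled-up value, but few spots were left out by this, and brightness was not used, so saturated spots are not known. Slopes of 0 intron indices passed over 5 to 30 min (limma, 30 at an unadjusted p under 0.05), so a fixed difference between treated and untreated RNA that does not depend on time in ethanol cannot be told apart from a change complete by 5 min. A biological effect of ethanol stays open and untested beyond these values.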

How the results depend on the processing

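The alternatives were planned, except leaving out piled-up spots, which was chosen after seeing the data and changed no call or count of a comparison beyond 1.5 times. Of 903 values of comparisons outside the leave-one-out fits, 739 stayed the same, 104 moved, 34 became stronger, 20 weaker and 6 reversed. A count stayed the same if it lay within 1.5 times its main value. A list median of the deletions did so within 1 SD of the medians on both arrays, and a prp8-1 probe median within 1 SD over its time points. A test did so if it kept its side of the threshold, and its direction where the main result passed. Of the values of named genes, 1080 under leave-one-out and 2093 under other settings stayed the same, 65 became weaker and 2 reversed. Signal over background is unknown, so what dim probes could show is not limited by a known floor. Unless said otherwise the cause was not tested.

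A minimum absolute mean of 0.5 left 158 probes, 42 intron and 12 junction indices in wild type in 3-AT, 122, 20 and 9 in the gcn2 deletion, 45, 8 and 3 in their direct comparison, 506 probes and 68 junction indices in prp8-1, 434, 93 and 77 in ethanol, 15, 2 and 2 for the difference between wild type and the gcn2 deletion, and 83 probes in common over the deletions, by construction. The first 3 time points, with fewer samples, gave 268, 94 and 2 in wild type in 3-AT, 12, 1 and 0 in the gcn2 deletion (42 junction indices at an unadjusted p under 0.05, limma), 397 probes and 33 junction indices in the direct comparison and 105 junction indices in prp8-1. The last 3 gave 384, 34 and 43 in the direct comparison and 22, 7 and 2 for the difference. Without a slope the gcn2 deletion gave 472 probes and 84 intron indices, the direct comparison 485 and 61, and the difference 0, 0 and 2 (limma, with 209 probes and 32 intron indices at an unadjusted p under 0.05). Intron minus junction in place of intron minus exon gave 149 genes (131 higher, 18 lower) in wild type in 3-AT, 140 (103, 37) in the gcn2 deletion, 66 (29, 37) in the direct comparison, 209 (198, 11) in prp8-1 and 177 (88, 89) in ethanol. The direct arrays in place of the difference gave 744, 98 and 76. With trend and robust eBayes 71 probes moved in common.

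Leave-one-out ranges were 66 to 357 probes, 5 to 40 intron and 0 to 16 junction indices for the difference, with the named time points given beside the result above, 49 to 80 junction indices in the direct comparison (49 without 10 min) and 68 to 166 probes in common (68 without rrp6, 80 without rai1, 89 without rtt103, 93 without upf1). By limma, 43 and 41 junction indices of the difference had an unadjusted p under 0.05 in the fits with 0. For ribosomal protein minus other genes, 5 values allow no exact p under 0.0625, so a lost threshold says nothing about stability. The ranges were 0.182 to 0.255 (intron), -0.085 to -0.065 (junction) and 0.183 to 0.238 (exon) in wild type in 3-AT, 0.173 to 0.241, -0.13 to -0.109 and 0.151 to 0.187 in the gcn2 deletion, -0.167 to -0.108 (junction) and 0.576 to 0.763 (exon) in prp8-1, and -0.319 to -0.281 (intron) and 0.266 to 0.317 (exon) in ethanol.

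With the time point as a replicate block the difference gave 11 junction indices, and 189 probes passed in both fits. The time points of both strains share the minute of sampling, and no label says that they share a culture, batch or day. Their pairing was checked by the correlation of deviations from the linear trend of each course, which was -0.02, -0.21, 0.08, 0.02, 0.18 and 0.27 by time, above 0.1 at 2 of 6, and 0 samples correlated best with their own time.

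Camera with an estimated correlation lost its calls in wild type in 3-AT for ribosome biogenesis (0.422), heat shock (0.331) and housekeeping introns (0.331), in the gcn2 deletion for ribosome biogenesis and housekeeping introns (0.162 each), in the direct comparison for ribosome biogenesis (0.527) and heat shock (0.071), in prp8-1 for ribosome biogenesis (0.26), and in ethanol for ribosomal proteins and ribosome biogenesis (0.5 each) and splicing factors (0.39). For prp8-1, ribosomal proteins and the lists of genes with introns are description, so their lost camera calls are left out here. Fry, which tests whether a list moves on balance and not against other genes, turned the direction for snoRNA hosts in the gcn2 deletion (0.0293), targeted genes in the direct comparison (0.000613), decay factors in prp8-1 (0.0231) and housekeeping introns in ethanol (0.000724). It passed where camera did not, in wild type in 3-AT for ribosomal proteins (0.0209), snoRNA hosts (0.00885), autoregulated and targeted genes (0.00172 each) and meiotic genes, decay and splicing factors (0.000273 each), and in the gcn2 deletion for ribosomal proteins (0.04), heat shock (0.049), autoregulated (1.57e-05), meiotic (0.0014) and targeted genes (0.00518), decay factors (5.09e-05) and splicing factors (0.00209). The same held in the direct comparison for ribosomal proteins (0.0161), snoRNA hosts (0.00542), autoregulated genes (0.00088), decay factors (0.00119) and splicing factors (0.000331). In prp8-1 it held for heat shock (1.59e-05), targeted genes (0.00132) and splicing factors (0.0424). In ethanol it held for heat shock and snoRNA hosts (0.000251 each), meiotic genes (0.0117), targeted genes (0.000724) and decay factors (0.000746). For the prp8-1 lists of genes with introns, fry gave 0.00119 for snoRNA hosts, 0.00132 for autoregulated genes and 0.000822 for meiotic genes. These 3 values are description and decide nothing, because this strain helped to define the exon probes that give the levels.

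Arrays with the treated or mutant sample in Cy3 alone took the exact p of the ribosomal protein minus other intron index in wild type in 3-AT to 0.0625, with a larger difference (0.239). They weakened the junction (-0.021) and exon (-0.025) medians there. The ribosomal protein minus other junction index in prp8-1 became smaller in size (-0.101 against -0.141, as description). The same arrays reversed the exon median of the direct comparison (0.001) and AMA1 in prp8-1 (0.141), and moved the prp8-1 junction median to -0.207. Members past the threshold became 5 meiotic genes in wild type in 3-AT, 13 ribosome biogenesis and 5 meiotic genes in the direct comparison and 2 decay targets in ethanol. The difference gave 128, 6 and 0 (40 junction indices at an unadjusted p under 0.05, limma), and 538 probes moved in common. Cy5 alone made stronger the junction medians of the gcn2 deletion (-0.114) and of the direct comparison (-0.092), and ribosomal protein minus other genes in ethanol (junction, -0.081), and raised that difference in prp8-1 (intron, 0.724, as description). It weakened the junction median in ethanol (0.066), reversed the exon median there (-0.004) and UBC12 in prp8-1 (0.216), and moved the prp8-1 junction median to -0.034. Members became 3 meiotic genes in the gcn2 deletion, and 2 decay targets and 4 meiotic genes in ethanol. The difference gave 6 intron and 8 junction indices, and 404 probes moved in common. For ribosomal protein minus other intron indices, the exact p was also 0.0625 with means over genes in the gcn2 deletion (0.182) and with a median over spots in wild type in 3-AT, where the difference itself hardly moved (0.213).

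These list medians of the deletions moved by more than 1 SD of the medians on both arrays. With Cy3 alone they were, for heat shock, 0.343 (rai1), 0.085 (rrp6), 0.616 (ski2) and 0.897 (xrn1), for snoRNA hosts 1.42 (rrp6), 0.148 (rtt103) and 0.066 (upf1), for meiotic genes -0.129 (rrp6), 0.065 (rtt103) and -1.07 (upf1), for ribosomal proteins 0.018 (rtt103), 0.113 (upf1) and -0.069 (xrn1), for ribosome biogenesis -0.093 (rtt103) and -0.433 (xrn1), and for autoregulated genes -0.013 (ski2). With Cy5 alone they were, for heat shock, 0.337 (rai1) and 0.943 (xrn1), for meiotic genes -0.011 (rai1) and 0.136 (rtt103), for ribosome biogenesis -0.102 (rtt103) and -0.644 (upf1), for snoRNA hosts 0.116 (ski2), for ribosomal proteins 0.079 (upf1) and -0.124 (xrn1), and for autoregulated genes 0.409 (upf1). Means over genes were, for heat shock, 0.377 (rai1) and 0.965 (xrn1), for ribosomal proteins 0.047 (rrp6), 0.12 (upf1) and -0.087 (xrn1), for snoRNA hosts 1.141 (rrp6) and 0.101 (upf1), for meiotic genes -0.057 (rrp6) and 0.078 (rtt103), for ribosome biogenesis -0.105 (rtt103), and for autoregulated genes 0.403 (upf1). A median over spots gave 1.215 (rrp6) and 0.151 (rtt103) for snoRNA hosts, -0.074 (rrp6) for meiotic genes and -0.151 (rtt103) for ribosome biogenesis, and median-centred arrays 0.35 (rai1) for heat shock and -0.156 (rtt103) for ribosome biogenesis.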

Other observations

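The sets of genes in this part were chosen after their values were seen, and none was planned. Genes of tRNAs, which the comparisons above do not describe as a group, were higher in ethanol, if its ratios run as treated over untreated. The median level of 24 mitochondrial tRNA genes was 0.61, with 22 higher and 0 lower (limma), and that of 40 nuclear ones 0.78, with 26 higher and 11 lower, both at percentile 100 among random lists. Single genes reached 2.36 in tS(UGA)Q2, 2.33 in tK(UUU)Q and 2.24 in tW(UCA)Q.

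The medians of the same genes were below 0 in every other course, though many single genes did not pass, and with the ethanol ratios turned its medians would be below 0 as well. In wild type in 3-AT the medians were -0.26 for mitochondrial (0 higher and 17 lower) and -0.17 for nuclear tRNA genes (2 and 23), in the gcn2 deletion -0.24 (0 and 13) and -0.18 (1 and 24), in the direct comparison -0.13 (1 and 13) and -0.21 (0 and 31), and in prp8-1 -0.37 (0 and 19) and -0.41 (1 and 35). Without XRN1 they were -0.59 and -0.62, without RAI1 the nuclear ones -0.40, and without RRP6 the mitochondrial ones -0.35. Other values of the deletions were smaller or went the other way, with nuclear tRNA genes at 0.12 (percentile 100) in the rtt103 deletion, 0.04 (percentile 91) without SKI2, -0.044 without UPF1 and -0.097 without RRP6, and mitochondrial ones at 0.057 without RAI1, -0.014 without SKI2, -0.015 in the rtt103 deletion and -0.16 without UPF1. The cDNA primer was not given in the sources used here, and the share of tRNA in the labelled RNA is not known.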
